A study of Mus musculus with 6 samples.

How the data were processed

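The samples were livers of male C57BL/6 mice, 8 weeks old at the start per the labels' protocols. A group of 3 samples came from mice given vehicle and the other group of 3 from mice given Vascepa. Vascepa is icosapent ethyl, the purified ethyl ester of the omega-3 fatty acid eicosapentaenoic acid. Each was given for 7 days and was followed by 6 weeks of high-fat diet. Total RNA was extracted with a silica column kit and hybridised as biotin-labelled target to Affymetrix GeneChips, 6 arrays in all, per the labels' protocols. The sample titles number the replicates of each group from 1 to 3. No label says that the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

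The authors deposited log2 expression values, 1 per transcript cluster and array, in a series matrix. Per the submitters' processing notes, they were made with Affymetrix Expression Console and RMA, whose versions are not given in the sources used here. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of a transcript cluster on the log2 scale. It compresses differences at the dim end, and its normalization assumes that the distribution of levels is the same on every array. The table held 41345 probes (transcript clusters) with no missing values. No scanner files were used here, and no scan dates or slides were known, so batches could not be tested.

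Gene names came from the platform annotation given with the data. Of the 41345 probes, 23521 had 1 gene symbol, 1814 had several and 16010 had no entry, which leaves them unnamed here. Symbols were updated by gene ID for 23328 of the single-symbol probes through a RefSeq gene table of the mouse assembly GRCm38.p6, giving 22180 distinct symbols. The sources used here name no genome build for the array, so that table served only for names, gene classes and gene span, and no coordinates are given. Probes with several symbols were not used to name a gene. This removed members of near-identical families, among them Cyp4a10 and Saa1, which were not analysed here.

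The comparison was Vascepa against vehicle, 3 arrays against 3, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values with no further normalization and no covariate. Probes with exactly 1 symbol and a mean over the 6 arrays at or above the median of all probes (2.65 on the log2 scale) were kept. Each gene was represented by its probe with the highest mean, which left 13493 genes. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Counts at an unadjusted p under 0.05, with and without a fold of at least 1.5, were kept as descriptions. Differences are Vascepa minus vehicle on the log2 scale, with limma's moderated standard error (SE).

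Before the data were examined, 34 gene lists were written from general knowledge of liver metabolism, zonation, sex bias, inflammation and of other cell types that a piece of liver could hold. The 33 lists with at least 5 members among the 13493 genes were tested with limma's camera at its preset correlation of 0.01. Camera compares a list with all other genes, and p-values were adjusted over the 33 lists. The same lists were tested with camera at a correlation estimated for each list, and with fry, which asks whether the genes of a list move on balance in the same direction. Members were matched by current symbol, or by an older symbol where the name given was not a current symbol. G6pc1 and Rigi carry the older symbols G6pc and Ddx58 in these tables and were matched by hand, after a first pass over the data. Several genes belong to more than 1 list, for example Cd36, Plin2 and Acot3. The number of members past the threshold was also counted with p adjusted over the list alone.

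The genes named in the text followed a rule set at the same time. In each direction it took up to 12 genes past the adjusted threshold whose groups did not overlap, filled up by smallest p from genes with a fold of at least 1.5 and no overlap. Since no gene passed, all 24 places came from the second step. Predicted genes, clone names, small RNAs and receptor families were left out of these places. In every list described, the 2 members with the smallest p were named, and Fgf21, Ppara, Srebf1, Fasn, Scd1, Cpt1a, Cd36, Cyp7a1, G6pc and Pck1 were named whatever their values. Genes named beyond this rule are said to have been chosen after their values were seen.

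The procedure was tested on 20 simulated data sets of this comparison with 13493 genes, 200 of them changed. At a log2 difference of 1 it recovered 37.5% of changed genes and at a difference of 2 it recovered 97.2%, with 6.02% false calls among all calls. Shifted lists were called in 100% of cases and unshifted lists in 0.667%. The simulated noise was independent between genes, while genes of a list here moved together, with an estimated correlation of 0.46 in pericentral genes. The simulated rates therefore do not carry over to the lists of these data. The rates for single genes may not carry over either, since these arrays varied along a shared axis that the simulation left out.

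The alternatives tried were no intensity filter, a filter at the 75th percentile, the mean of a gene's probes, every probe tested, quantile normalization again, centring of each array on its median, an intensity trend with a robust prior, array quality weights, the replicate number as a block, each replicate left out in turn, and for lists the estimated correlation, ranks and fry. A small RNA score was added as a covariate after seeing the data. It is the mean level of 68 small nucleolar RNA genes on each array. Figures were drawn with matplotlib 3.10.9.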

Results

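Liver gene expression was measured on 6 arrays, 3 from mice given vehicle and 3 from mice given Vascepa, the ethyl ester of the omega-3 fatty acid eicosapentaenoic acid. Dosing lasted 7 days and was followed by 6 weeks of high-fat diet in both groups, so the comparison asks how livers differed on this diet after earlier Vascepa. Both groups had the diet, and no group without it was analysed here. Of the genes with a probe of their own, 13493 lay at or above the median intensity and were compared. Pairs of arrays correlated at r between 0.906 and 0.986 across genes. Small nucleolar RNA levels differed more within groups than between them. Their mean log2 level was 5.80, 6.69 and 6.06 on the vehicle arrays and 5.67, 6.82 and 7.36 on the Vascepa arrays. Vascepa replicate 3 stood farthest from the other arrays, with a mean r of 0.938.

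A proton pump subunit, a peroxisomal transporter and cytochrome P450 genes were among the lower genes with the smallest p. Cyp2b13 and Cyp2b9, cytochrome P450 genes used more in female than in male mouse liver, were 3.66-fold and 2.99-fold lower (log2 difference −1.87 ± 0.32 and −1.58 ± 0.35, SE). Abcd2, a peroxisomal transporter of very long-chain fatty acids, was 2.61-fold lower, from a mean of 6.98 to 5.60 (−1.39 ± 0.23). Cyp4a14, a fatty acid hydroxylase gene driven by PPAR alpha, was 2.01-fold lower, from 10.35 to 9.34 (−1.01 ± 0.19). Atp6v0d2, a subunit of the proton pump of lysosomes, was 2.56-fold lower, from 4.12 to 2.76 (−1.36 ± 0.22). Groups that do not overlap were part of the rule that chose these 5 genes, and none passed the adjusted threshold (limma, adjusted p = 0.976 for each).

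The other 7 of the 12 lower genes with the smallest p belong to varied functions. Tmem176a and Tmem176b, neighbouring genes of related membrane proteins found in many immune cells, differed by −1.07 ± 0.20 and −0.76 ± 0.20. Pltp, the phospholipid transfer protein of plasma, differed by −0.78 ± 0.20 and Cyp2c38, a further cytochrome P450, by −0.87 ± 0.20. Dsg1c, a cadherin of desmosomes, differed by −0.96 ± 0.18. Unc119, a chaperone of lipid-modified proteins, differed by −0.81 ± 0.20, and Tmem184a by −0.89 ± 0.23. Cyp2b9 and Cyp2b13 are close relatives, as are Cyp4a14 and other Cyp4a genes, and binding of 1 copy's RNA to another's probes was not excluded.

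**Figure D1:**
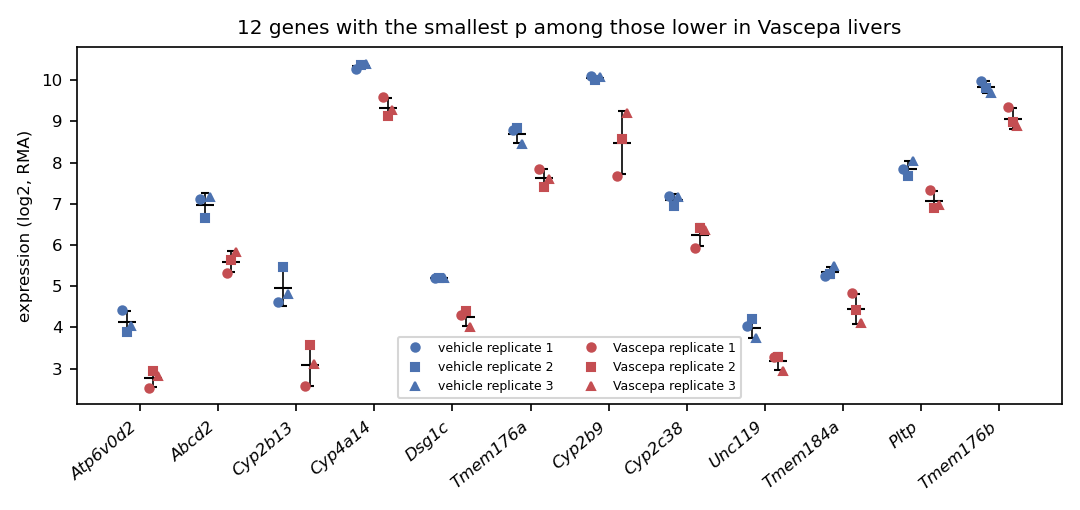
Log2 expression (RMA) of the 12 genes with the smallest p among those lower in Vascepa livers, with each point 1 array, blue for vehicle and red for Vascepa, and bars giving the group mean and SD of 3 arrays. The genes were chosen for groups that do not overlap, and the means are 10.06 and 8.48 for Cyp2b9 and 6.98 and 5.60 for Abcd2.

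Pseudogenes and members of multi-copy families were among the genes higher in Vascepa livers. Serpina4-ps1 and Adh6-ps1, which are pseudogenes, were 2.95-fold and 1.60-fold higher (1.56 ± 0.38 and 0.68 ± 0.17). Mettl7a3 differed by 1.12 ± 0.31 and Supt4b, a copy of a transcription elongation factor gene, by 1.06 ± 0.32. Zfp282, a zinc finger gene, differed by 0.93 ± 0.23 and Btbd35f1, of a multi-copy family, by 0.91 ± 0.20. Prh1, a salivary proline-rich protein gene, differed by 0.85 ± 0.22 and Amn, a partner in vitamin B12 uptake, by 0.84 ± 0.25. Elavl3 and Rims4, best known from neurons, differed by 0.74 ± 0.19 and 0.65 ± 0.19. Lsm11, of the histone RNA processing complex, differed by 0.70 ± 0.21 and Adgrf1, an adhesion receptor, by 0.59 ± 0.16. Most of the 12 were dim. The vehicle means of Lsm11 and Adgrf1, 2.57 and 2.44, lay under the filter level of 2.65, which their means over the 6 arrays passed. Adh6-ps1 and Serpina4-ps1 were the brightest in vehicle livers, at 7.27 and 5.15, with Mettl7a3 next at 3.96. Whether the dim genes were expressed in these livers was not tested. None of these 12 passed (limma, adjusted p = 0.976 for each), and relatives or copies of Supt4b, Mettl7a3 and Btbd35f1 may share their probes.

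Across all 13493 genes, limma called 0 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 362 genes, 141 higher and 221 lower, fewer than the 675 that chance gives. With a fold of at least 1.5 there were 168, 57 higher and 111 lower. With each array centred on its median, which moved the median difference of all genes by 0.10 from −0.063 to 0.037, this became 172, and the share that was higher went from 33.9% to 68.0%. The groups did not overlap in 1112 genes, 8.24% of those tested, against 10% by chance. Single arrays moved these counts. The 362 became 198 without vehicle replicate 1, 141 without vehicle replicate 3, 221 without Vascepa replicate 2 and 2018 without Vascepa replicate 1, which also took the 168 to 1691. Array quality weights, with a weight of 39.5 on Vascepa replicate 2 and at most 2.33 on the others, gave 4100 genes at the adjusted threshold, and the small RNA score as a covariate, added after seeing the data, gave 2, Cyp2b13 and Cyp2b9 (limma, adjusted p = 0.0306 and 0.0317).

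Among 33 gene lists, 9 lay lower in Vascepa livers and 3 higher relative to all other genes by limma's camera at its preset correlation. None of the 12 held with an estimated correlation, where the lowest adjusted p was 0.268, or with fry, where it was 0.121. Fry's test for change in either direction passed for female-biased genes and skeletal muscle markers, at adjusted p = 0.0475 and 0.0229. Over all genes no member of any list passed, so the values of members are given below without a call. A gene can sit in several lists, and their results are not independent.

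Targets of PPAR alpha, the receptor that drives fatty acid oxidation in the liver, were lower in Vascepa livers. Of 22 tested members 19 were lower and 3 higher, with a median log2 difference of −0.40 (camera adjusted p = 5.51e-06). With an estimated correlation the adjusted p was 0.270. Adjusted over the list alone, 1 member passed, Cyp4a14. Acaa1b, a peroxisomal thiolase, differed by −0.58 ± 0.17. Vnn1, Acot2 and Crat, chosen after their values were seen, differed by −0.81 ± 0.24, −1.07 ± 0.35 and −0.61 ± 0.23. Relative to the vehicle mean, the list's median lay at −0.40, −0.24 and −0.39 in Vascepa replicates 1, 2 and 3, and at −0.23 in vehicle replicate 1. Mitochondrial beta-oxidation enzymes, many of them also targets of the receptor, did not pass, with 14 of 19 lower and a median of −0.12 (camera adjusted p = 0.519). Hadh and Etfdh differed by −0.30 ± 0.17 and −0.30 ± 0.25.

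Genes with a sex bias in mouse liver lay in opposite directions in these male mice. All 10 female-biased genes above the intensity filter were lower in Vascepa livers, with a median of −0.59 (camera adjusted p = 7.91e-06, and adjusted p = 0.270 with an estimated correlation). The list had 17 members with a probe of their own, and those under the filter were not tested. Adjusted over the list alone, 3 passed, Abcd2, Cyp2b13 and Cyp2b9. Of 15 male-biased genes 13 were higher, with a median of 0.38 (camera adjusted p = 0.000180, and adjusted p = 0.570 with an estimated correlation). Hsd3b5, a steroid dehydrogenase of male liver, read 6.26, 5.93 and 5.87 on the vehicle arrays and 8.25, 8.45 and 5.87 on the Vascepa arrays, 2.83-fold higher in the mean (SE 0.62 on the log2 scale). Mup21, of the major urinary protein family, differed by 0.70 ± 0.28. The male-biased shift was carried by Vascepa replicates 1 and 2, whose medians lay 0.97 and 0.71 above the vehicle mean, while Vascepa replicate 3 lay at −0.31. Without Vascepa replicate 1 this list's adjusted p was 0.168.

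**Figure D2:**
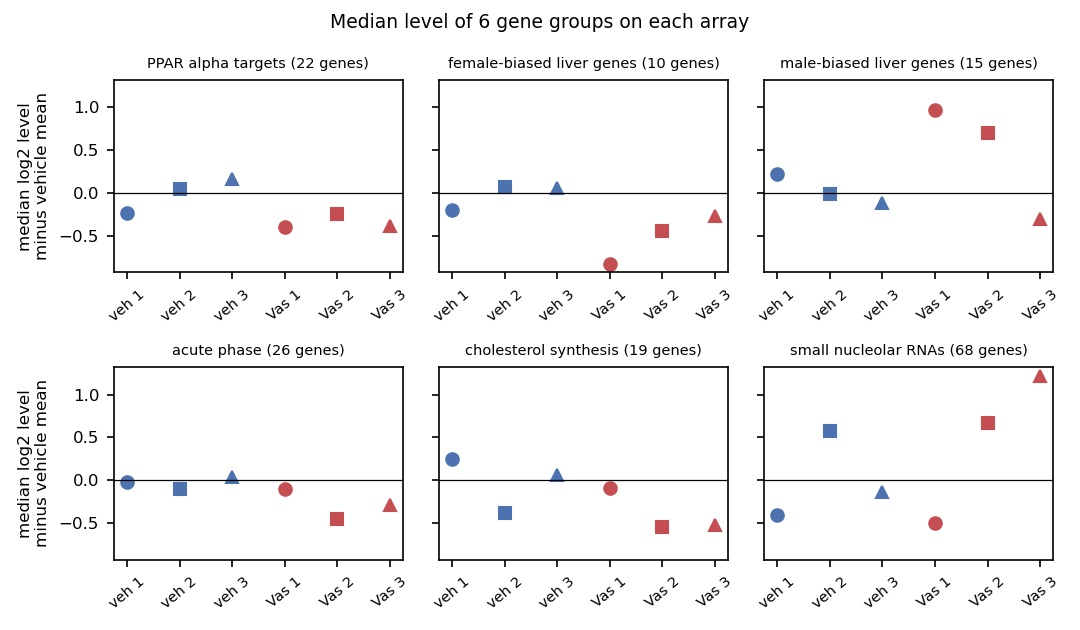
Median level of 5 gene lists and of small nucleolar RNAs on each array, as log2 difference from the vehicle mean, with each point 1 array, blue for vehicle and red for Vascepa. Female-biased genes lie below 0 on all 3 Vascepa arrays (−0.83, −0.45 and −0.27) and at −0.20 on vehicle replicate 1, while male-biased genes lie at 0.97, 0.71 and −0.31 and small nucleolar RNAs spread within both groups.

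Genes of lipid synthesis and storage were lower as groups in Vascepa livers. All 19 measured cholesterol synthesis genes were lower, with a median of −0.35 (camera adjusted p = 3.17e-05, and adjusted p = 0.570 with an estimated correlation). Insig1, a sterol sensor, and Nsdhl, a sterol dehydrogenase, differed by −0.62 ± 0.26 and −0.57 ± 0.24. In lipid droplet genes 16 of 20 were lower, with a median of −0.34 (camera adjusted p = 0.000814, and adjusted p = 0.570 with an estimated correlation). Plin4 and Cidec, which coat lipid droplets, differed by −0.65 ± 0.22 and −0.95 ± 0.39, and without Vascepa replicate 1 the list's adjusted p was 0.124. In lipogenesis 20 of 24 genes were lower, with a median of −0.28 (camera adjusted p = 0.0300, and adjusted p = 0.928 with an estimated correlation). Its members Rdh11 and Dgat1, which makes triglyceride, differed by −0.81 ± 0.34 and −0.61 ± 0.32. Without Vascepa replicate 3 these 2 genes differed by −0.51 and −0.22. The lipogenesis call was lost without vehicle replicate 1, vehicle replicate 3, Vascepa replicate 2 or Vascepa replicate 3, at adjusted p = 0.187, 0.735, 0.114 and 0.346. It was also lost with the small RNA score, where the median was −0.10, and with the 75th percentile filter (camera adjusted p = 0.618 and 0.198). Lipogenesis medians were lowest on arrays high in small nucleolar RNAs, at −0.60, −0.28 and −0.45 from the vehicle mean on Vascepa replicates 3 and 2 and vehicle replicate 2. Cholesterol synthesis lay at −0.52, −0.54 and −0.38 on these arrays and at −0.092 on Vascepa replicate 1.

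Acute phase genes, which the liver switches on in inflammation, were lower in the mean of Vascepa livers in 25 of 26 cases, with a median of −0.32 (camera adjusted p = 5.64e-05, and adjusted p = 0.268 with an estimated correlation). The fall was uneven between arrays. On Vascepa replicates 1, 2 and 3 the list's median lay at −0.11, −0.45 and −0.29 from the vehicle mean. On vehicle replicates 1, 2 and 3 it lay at −0.023, −0.10 and 0.037. Il1rn, the interleukin-1 receptor antagonist, and Orm2, a plasma orosomucoid, differed by −0.62 ± 0.19 and −1.28 ± 0.46. Lcn2 differed by −1.60 ± 0.60, and it, Hamp and Saa2 were chosen after their values were seen. Hamp, which encodes hepcidin, was the exception at 0.82 ± 0.47. Saa2, the serum amyloid gene, was uneven within both groups, at 7.90, 8.04 and 11.37 on the vehicle arrays and 6.29, 5.99 and 11.42 on the Vascepa arrays. Markers of Kupffer cells, the macrophages of the liver, were lower in 16 of 20 cases, with a median of −0.17 (camera adjusted p = 0.0292, and adjusted p = 0.724 with an estimated correlation). Vsig4 and Cd68 differed by −0.53 ± 0.18 and −0.54 ± 0.20. The Kupffer call was lost without vehicle replicate 1, Vascepa replicate 1 or Vascepa replicate 2, at adjusted p = 0.151, 0.884 and 0.0618. Quantile normalization again, centring, the trended prior, array weights and the replicate block also ended it (adjusted p = 0.278, 0.0900, 0.0568, 0.172 and 0.0581). The median was −0.055 with quantile normalization again and −0.066 with centring. Cytokines and chemokines did not pass, with 17 of 23 lower and a median of −0.19 (camera adjusted p = 0.152), and passed without Vascepa replicate 3, without an intensity filter and with the small RNA score (adjusted p = 0.000933, 0.0230 and 0.00299). Ccl2 and Il1b, signals of macrophage recruitment and activation, differed by −0.85 ± 0.26 and −0.81 ± 0.26.

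Genes of glucose metabolism and insulin signalling were lower in 23 of 25 cases, with a median of −0.23 (camera adjusted p = 0.0300, and adjusted p = 0.928 with an estimated correlation). G6pc, the last enzyme of glucose output, and Trib1 differed by −0.57 ± 0.27 and −0.49 ± 0.24. The call depended on G6pc, matched to the list by its older name after the data had been seen, and without it the adjusted p was 0.0628. It was also lost without vehicle replicate 1 or vehicle replicate 3, at adjusted p = 0.187 and 0.0728, and without Vascepa replicate 3 the direction turned (adjusted p = 0.779). Its medians ran opposite to the small nucleolar RNAs, at 0.26, −0.13 and −0.82 on the Vascepa arrays and 0.25, −0.25 and 0.14 on the vehicle arrays. With the small RNA score camera turned upward (adjusted p = 0.974), and array weights and the 75th percentile filter also ended the call (0.107 and 0.198). Pericentral hepatocyte genes, those used near the central vein, were lower in 16 of 17 cases, with a median of −0.26 (camera adjusted p = 0.0292, and adjusted p = 0.928 with an estimated correlation). Slc13a3 and Axin2, a Wnt target, differed by −0.75 ± 0.41 and −0.46 ± 0.25. This call was lost without vehicle replicate 1, Vascepa replicate 2 or Vascepa replicate 3, at adjusted p = 0.148, 0.0552 and 0.997, and with the small RNA score, array weights or the 75th percentile filter, at 0.618, 0.173 and 0.202. Periportal genes, of the opposite side of the lobule, did not pass, with 9 of 13 lower (camera adjusted p = 0.5003), with Ctsc at −0.42 ± 0.23 and Hsd17b13 at −0.28 ± 0.17. General hepatocyte markers had a median of −0.13 with 15 of 16 lower (camera adjusted p = 0.185, or 0.0273 without a filter and 0.0495 with quantile normalization again), and Serpinc1 and F2 differed by −0.24 ± 0.20 and −0.21 ± 0.17. Relative to the vehicle mean, the hepatocyte markers lay at −0.34 on Vascepa replicate 3, −0.061 on Vascepa replicate 2 and 0.011 on Vascepa replicate 1.

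Markers of skeletal muscle and pancreas were higher in Vascepa livers. Of 7 skeletal muscle genes 6 were higher, with a median of 0.36 (camera adjusted p = 0.000586, and adjusted p = 0.268 with an estimated correlation). Acta1, skeletal actin, was 4.08 in vehicle and 4.61 in Vascepa livers (0.52 ± 0.18), and Mb, myoglobin, differed by 0.41 ± 0.21. All 5 pancreatic acinar genes were higher, with a median of 0.29 (camera adjusted p = 0.00872, and adjusted p = 0.270 with an estimated correlation). Clps, the cofactor of pancreatic lipase, and Ctrb1, a digestive protease, differed by 0.52 ± 0.25 and 0.29 ± 0.21. The vehicle mean of Clps, 2.51, lay under the filter level of 2.65, and it was tested only because its Vascepa mean was 3.03. Without Vascepa replicate 2 the acinar list's adjusted p was 0.0572, and without an intensity filter, over 13 genes, its median was 0.0087 (adjusted p = 0.256).

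**Figure D3:**
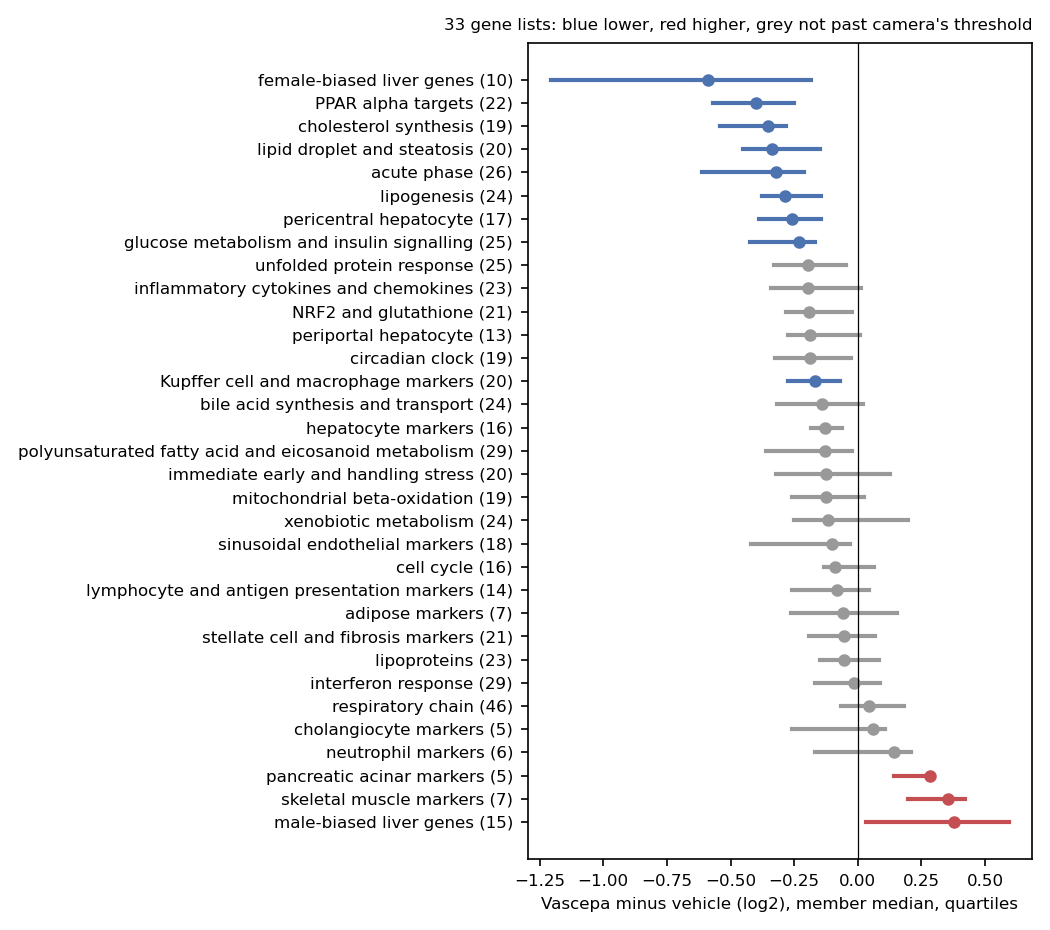
Vascepa minus vehicle log2 difference of 33 gene lists, with each point the median of a list's tested members and each bar their quartiles. The number of tested members is in brackets. The 9 blue lists are lower and the 3 red ones higher by camera at its preset correlation, from female-biased genes at −0.59 to male-biased genes at 0.38, and grey lists did not pass.

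None of the central genes of lipid and glucose metabolism passed. Fgf21, a fasting hormone of the liver, differed by 0.0063 ± 0.25, Ppara by −0.38 ± 0.30 and Cpt1a, the gate of mitochondrial fatty acid entry, by −0.46 ± 0.41. Srebf1, Fasn and Scd1, of fatty acid synthesis, differed by −0.21 ± 0.46, −0.33 ± 0.55 and −0.16 ± 0.42. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.13 ± 0.47 and Pck1, of gluconeogenesis, by −0.27 ± 0.36. Cd36, a fatty acid uptake receptor, stood apart at −0.77 ± 0.32, from 8.77 to 8.00, and missed the threshold (limma, adjusted p = 0.976). Its difference was −0.43 without Vascepa replicate 1 and −1.07 without Vascepa replicate 3. In others of these genes, signs turned when single arrays were left out. Without Vascepa replicate 3 the difference was 0.010 in Cpt1a, 0.14 in Pck1, 0.27 in Srebf1, 0.0035 in Fasn and −0.22 in Fgf21. Without vehicle replicate 1 it was 0.071 in Srebf1, 0.019 in Fasn, −0.062 in Fgf21 and −0.39 in Cyp7a1. Scd1 was 0.25 without vehicle replicate 3, Fgf21 was −0.0090 without vehicle replicate 2, and Cyp7a1 was −0.012 and −0.064 without Vascepa replicates 1 and 2.

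Other metabolic lists did not pass. Xenobiotic metabolism had a median of −0.12 with 15 of 24 lower (camera adjusted p = 0.362), and adjusted over the list alone 3 members passed, Cyp2b13, Cyp2b9 and Cyp2c38. Genes of polyunsaturated fatty acid and eicosanoid metabolism, the pathways that handle the drug's own fatty acid, were lower in 24 of 29 cases with a median of −0.13 (camera adjusted p = 0.383). Ephx1 and Lta4h, which act on epoxides and leukotrienes, differed by −0.48 ± 0.25 and −0.51 ± 0.29. Bile acid genes had a median of −0.14 (camera adjusted p = 0.579), with the transporter Slco1a1 at 0.69 ± 0.36 and Cyp8b1, a sterol hydroxylase, at −0.46 ± 0.27. Lipoprotein genes had a median of −0.054, above 0 with centred arrays (camera adjusted p = 0.941), with Pltp lower, as given above, and Apoa4 at 0.43 ± 0.23. NRF2 and glutathione genes had a median of −0.19 (camera adjusted p = 0.165, or 0.0496 without a filter), with Gstm3 at −0.81 ± 0.36 and Osgin1 at −0.61 ± 0.30.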

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

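The small RNA score was added after seeing the data. Over 93 named genes and all settings, the direction was kept in 1345 of 1367 refits, and 2 refits outside array weights reached the adjusted threshold. Kept directions are no separate support, since many of these genes were picked for groups that do not overlap or for the smallest p. All refits also reuse the same arrays. Where a call ended, the cause was not tested unless fewer samples or genes explain it, and signal over background limits the dim genes most. Array quality weights gave 4100 genes at the adjusted threshold, 5902 at an unadjusted p under 0.05 and 1289 with a 1.5-fold difference, which may be an artefact of a weight of 39.5 on Vascepa replicate 2 against 0.178 to 2.33 on the others. The small RNA score as a covariate gave 2, and 818 at the unadjusted threshold. Without an intensity filter these 2 counts (unadjusted, and with 1.5-fold) were 757 and 288, at the 75th percentile 106 and 66, and with every probe tested 581 and 359. Left-out replicates gave 141 to 2018, 116 to 1691 and, for lists, 8 to 14.

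Same-numbered replicates deviated together at r = 0.61, 0.11 and −0.13 and vehicle 2 correlated best with Vascepa 3 (0.57), so these values show no consistent pairing by number. The strong variation between arrays within each group could hide a pairing, so none is excluded. The replicate block gave 271 genes with a 1.5-fold difference and 0 at the adjusted threshold, put Kupffer markers at 0.0581 and changed no other called list, while unfolded protein response genes passed as lower and the respiratory chain as higher (0.0357 each).

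With an estimated correlation and with fry, 0 lists passed. Adjusted p were 0.270 and 0.212 for PPAR alpha targets, 0.928 and 0.700 for lipogenesis, glucose metabolism and pericentral genes, 0.570 and 0.564 for cholesterol synthesis, 0.570 and 0.418 for lipid droplets, 0.268 and 0.121 for acute phase and skeletal muscle genes, 0.570 and 0.700 for male-biased, 0.270 and 0.204 for female-biased, 0.724 and 0.552 for Kupffer and 0.270 and 0.250 for acinar genes. PPAR alpha, female-biased, cholesterol, acute phase, male-biased, skeletal muscle and lipid droplet lists kept their call in the other settings that tested them, except male-biased and lipid droplet genes without Vascepa replicate 1. At the 75th percentile skeletal muscle and acinar genes had too few members to test. At the 75th percentile, the adjusted p was 0.198 for lipogenesis and glucose and 0.202 for pericentral genes. With quantile normalization Kupffer was 0.278, with centring 0.0900, with the trended prior 0.0568. With array weights Kupffer was 0.172, pericentral 0.173 and glucose 0.107. With the small RNA score lipogenesis and pericentral genes were 0.618, glucose turned upward at 0.974 and the respiratory chain turned downward at 0.00299. Acinar genes without a filter were 0.256. Left-out replicates gave adjusted p of 1.44e-05 to 0.735 for lipogenesis, 0.00187 to 0.779 for glucose, 5.82e-07 to 0.124 for lipid droplets, 4.29e-18 to 0.168 for male-biased, 0.00420 to 0.997 for pericentral, 4.12e-06 to 0.884 for Kupffer and 0.00981 to 0.0572 for acinar genes.

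Signs turned in Fgf21 with weights (−0.13) and with the score (−0.16), in Srebf1, Fasn, Scd1 and Pck1 with the score (0.22, 0.17, 0.034 and 0.018), and in Pck1 and Ngp with weights (0.099 and −0.050). Left-out replicates gave −0.22 to 0.21 for Fgf21, −0.56 to 0.27 for Srebf1, −0.93 to 0.019 for Fasn, −0.68 to 0.25 for Scd1, −0.86 to 0.010 for Cpt1a, −0.39 to 0.46 for Cyp7a1, −0.54 to 0.14 for Pck1 and −0.022 to 0.45 for Ngp.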

Other observations

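Among the tests below, the small RNA score, the leading-component tests other than gene span, the hepatocyte test, the tests of muscle and pancreas apart and the lists around Atp6v0d2 and Cdkn1a were chosen after the results that prompted them were seen. Unfolded protein response, clock, immediate early, respiratory chain, interferon and cell cycle genes gave no call at camera's threshold in the comparison as fitted. Unfolded protein response genes were lower in 22 of 25 cases (median −0.19, camera adjusted p = 0.195), with Dnajb9 at −0.44 ± 0.21 and Herpud1 at −0.34 ± 0.24. The list passed without vehicle replicate 2 or vehicle replicate 3 (adjusted p = 0.00373 and 0.0361) and without a filter (0.0255). Clock genes had a median of −0.19 (camera adjusted p = 0.671), with Bhlhe40 at −0.52 ± 0.32 and Cry2 at −0.41 ± 0.31. Immediate early genes, which respond to handling, had a median of −0.13 (camera adjusted p = 0.564), with Egr1 at −0.53 ± 0.21 and Jun at −0.66 ± 0.36. Respiratory chain genes had a median of 0.045 over 46 members (camera adjusted p = 0.146), with Atp5a1 at −0.25 ± 0.24 and Ndufa10 at −0.21 ± 0.22. That list passed as higher without vehicle replicate 2 or Vascepa replicate 1 (adjusted p = 0.00107 and 1.12e-05), at the 75th percentile (0.000241), with array weights (0.000129) and on ranks (0.0382). With the small RNA score it passed as lower (adjusted p = 0.00299). Interferon genes had a median of −0.016, above 0 with centred arrays or quantile normalization, and opposite directions in camera and fry (camera adjusted p = 0.941), with Gbp7 at −0.77 ± 0.35 and Irf7 at −0.38 ± 0.25. Cell cycle genes had a median of −0.088, above 0 with centred arrays (camera adjusted p = 0.929), with Ccnd1 at −0.50 ± 0.26 and Cdk1 at −0.40 ± 0.21.

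Among other cell types, sinusoidal endothelial markers were lower in 14 of 18 cases (median −0.10, camera adjusted p = 0.181, or 0.0255 without a filter), with Tie1 at −0.39 ± 0.17 and Pecam1 at −0.43 ± 0.20. Stellate cell and fibrosis markers had a median of −0.056, above 0 with centred arrays (camera adjusted p = 0.898), with Lum at −0.49 ± 0.25 and Bgn at −0.59 ± 0.45. Lymphocyte and antigen presentation markers had a median of −0.082, above 0 with centred arrays, while camera placed them upward (adjusted p = 0.941), and their leading members were higher, Ccr7 at 0.67 ± 0.23 and Ltb at 0.54 ± 0.23. Neutrophil markers had a median of 0.14 over 6 members (camera adjusted p = 0.5003), with Cxcr2 at −0.30 ± 0.20 and Ngp at 0.27 ± 0.27, or −0.022 for Ngp without Vascepa replicate 3. Cholangiocyte markers had a median of 0.059 over 5 members, under 0 with quantile normalization, upward in camera and downward in fry (camera adjusted p = 0.941), with Pkhd1 at −0.26 ± 0.20 and Sox9 at −0.43 ± 0.34. Adipose markers had a median of −0.057, above 0 with centred arrays (camera adjusted p = 0.993), with Car3 at −0.33 ± 0.22 and Aqp7 at −0.25 ± 0.18. Erythroid markers had 3 members above the intensity filter, too few to test, with a median of −0.094.

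Where camera is given for a list made after the data were seen, n counts genes, which are not independent replicates. Of the 10 splits of the 6 arrays into 3 and 3, all 10 give at least the real 0 genes at the adjusted threshold, as any count must, which says nothing about chance. The highest of the others was 1035. As many genes as the real 362 at an unadjusted p under 0.05 came from 4 of the 10 splits, with 3990 as the highest other, and as many as the real 168 with a 1.5-fold difference from 4, with 2663 as the highest other. List medians as large in size as the real ones came from 7 of the 10 splits for glucose metabolism, 4 for lipogenesis, male-biased and pericentral genes, 3 for cholesterol synthesis and Kupffer genes and 2 for female-biased genes. For the other 5 called lists it was 1, the real split. As many lists as the real 12 came from 2 of the 10, with 12 as the highest other. So few splits cannot give a share under 0.05. The split with 1035 genes set vehicle 1, vehicle 3 and Vascepa 1 against the rest, which parts the arrays at a small RNA score of at most 6.06 from those of at least 6.69, and points to a structure of the samples other than the treatment.

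The leading component of the 6 arrays, 64.4% of the variance, did not separate the groups. The groups overlapped on it, with a gap of −48.1, so it is not a uniform difference between the treatments. Overlap of 3 against 3 arrays cannot exclude that Vascepa contributed to it. RNA quality or small RNA recovery may underlie it, since the difference of Vascepa replicate 3 from replicate 1 fell with gene span across protein-coding genes (Spearman rho −0.342, across genes, which are not independent replicates), as did that of vehicle replicate 2 from replicate 1 (−0.345). Small nucleolar RNAs differed by 1.78 and ribosomal protein genes by 1.27 between those Vascepa arrays. An acute phase response in Vascepa replicate 3, prompted by its Saa2 level, stays open. A set of 9 constitutive members lay lower there (median −0.640), but over all 26 members 15 were lower and 11 higher than the mean of the other arrays, with Saa3 and Apcs, chosen after their values were seen, highest there.

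The lower PPAR alpha targets and female-biased genes, 31 genes with a median of −0.42, are the group a biologist may most want to follow up. A linear effect of the small RNA score does not account for most of that median, which was −0.369 with the score as a covariate. Both lists then stayed past camera's threshold at the preset correlation, but not with an estimated correlation (camera adjusted p = 0.368 and 0.158). The preset threshold cannot decide the question, since each list also passed it in splits other than the real one. The score may not capture the whole small RNA axis, so a part of the axis in the shift is not excluded. Cross-hybridisation within multi-copy families, set by gene name, does not account for all of the lower genes. The 21 members outside those families had a median of −0.33 (camera, n = 21 genes, p = 3.69e-06, or 0.0289 with an estimated correlation). That p is no support for the shift itself, since both lists were picked for being lower. Close relatives of members outside the named families were not checked. A lower share of hepatocytes stays open. Their markers had a median of −0.131, but 13 of the 16 lay above the 99th percentile of levels. A loss may be compressed there, which was not tested. An effect of Vascepa remains open as a hypothesis, since 5 of the 10 splits put each list past the threshold. The real split had the lowest p for both, but another split gave female-biased genes a larger median (0.60 against 0.59 in size), and single arrays cannot be tied to separate animals.

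The higher skeletal muscle and pancreatic acinar markers were weighed against technical sources. A general rise of dim probes is argued against, since random lists of the same size and level had a median of 0.010. The median of the 12 tested members, 0.32, lay at percentile 99.97 of 10000 such lists. That percentile is no support for the shift itself, since both lists were picked for being higher. Muscle or pancreas tissue as a common source missed a bound set in advance, a median of 0.2. All 27 measured members, dim ones included, had a median of 0.0919 (SE 0.058) with 16 higher. Of the 15 members under the intensity filter, 5 were higher, against 11 of the 12 tested members. Members near the floor may not register a small share of other tissue, so this source stays open. Apart, pancreas missed the bound with a median of 0.0087 over its 13 members, though all 5 members above the filter were higher. Muscle had a median of 0.30 with 9 of 14 higher. Both stay open. No biological explanation was tested.

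Atp6v0d2 is known from lipid-laden macrophages, and fewer such cells may lie behind its lower level. A list of 20 genes of these cells without it was lower (camera, n = 20 genes, p = 0.0310, or 0.0929 adjusted over 3 such lists), but not with an estimated correlation (p = 0.0782), which leaves that open. Other V-ATPase subunits did not pass as a list, with 11 of 16 lower and a median of −0.17 (camera, n = 16 genes, p = 0.121). That median is far from the −1.36 of Atp6v0d2, which argues against a like shift of the whole pump in the tissue as sampled. A shift within a small share of the cells could be diluted and is not excluded. Cdkn1a, chosen after its value was seen, differed by −1.54 ± 0.45. Of 20 other p53 targets 15 were lower, and camera placed the list downward without passing (camera, n = 20 genes, p = 0.319). Their median of −0.045 was no lower than that of all genes (−0.063). That gives lower p53 activity no clear support, but a p above the threshold at 3 against 3 does not exclude it. The bound set in advance on p was therefore wrong, and lower p53 activity stays open.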
